A study of Mus musculus with 4 samples.

How the data were processed

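RNA-seq was made from Lin– bone marrow cells of 4 mice, 2 per genotype, each mouse its own library. The deposited values are a signal per gene, gene read counts divided by a size factor for each library, per the file headers and the submitters' processing notes. Per the submitters' processing notes, Trim Galore 0.6.7, STAR 2.7.9a, featureCounts, SAMtools and DESeq2 were used on build mm39. Their settings, the annotation and the strand setting are not given in the sources used here. The table names its control columns as wild type, and they were taken as the samples labelled control by group and number. The table held 16673 genes, and the smallest sum of reads over the 4 libraries was 41, so genes with few reads had been left out before.

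Within each library all values were whole multiples of the value of 1 read (100% of values, within 0.1 read), so whole reads were recovered by division. They summed to 39199593 and 46673855 for control replicates 1 and 2 and to 28845037 and 30020188 for cKO replicates 1 and 2, with size factors of 1.08, 1.25, 0.857 and 0.870. A gene at 0 was given a floor of 3 reads per library (2.39 to 3.50 normalized counts), and folds against a group at 0 are lower bounds from that floor. Shares of reads carry Wilson 95% intervals. Replicates differed by far more than counting noise (chi-square per degree of freedom 327 for control and 42.2 for cKO), which excludes 1 library counted 2 times but not 2 libraries made from the same cells.

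The main test was limma 3.58.1 (R 4.3.3) on log2(normalized count + 1), empirical Bayes with a trend, over 16598 genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It is a model fitted across all genes. An exact permutation test of 2 against 2 cannot go below 0.33. The residual degrees of freedom were 2 and the prior 5.48. Gene lists were tested with limma's camera at a preset correlation of 0.01, over 35 of 36 lists with at least 5 tested members, and again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Counts adjusted over the list alone used the members' own p-values.

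The named genes follow a rule written before the data were examined, as were the lists, tests and alternatives. It took Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b and Tek. It then took up to 12 genes per direction past the threshold, with a mean of at least 50 and both libraries labelled cKO beyond both labelled control, leaving out predicted genes, Xist, Y genes and immunoglobulin or T cell receptor segments. Places left open were filled by the smallest p-values, given as values that did not pass. Last, it took up to 4 members with the smallest p-value for each called or lineage list. Some genes the rule takes are not reported here. The called genes outside the rule (Xist, the Y genes, Gm42047, Gm49980 and Igkv6-15), Eif3j1, Igkv4-63 and Ly6c2 were named after their values were seen.

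The alternatives were pseudocounts of 0.5 and 10, no filter and a mean of at least 50, rescaling by TMM, quantile normalization, empirical Bayes without a trend and robust, the replicate number as a block, each library left out, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads. edgeR called 12 genes on the recovered reads, 5 higher and 7 lower. A test with X and Y genes left out was added after seeing the data. Chromosomes were taken from GENCODE M21 (GRCm38) by gene symbol for 97.3% of genes, for membership and gene order only. It is another build than that of the reads, so no coordinates are given.

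The steps were tested on simulated data for cKO against control, with 16673 genes drawn from the real means, of which 16211 were tested and 200 changed. The limma step called 34% of 2-fold and 92% of 8-fold genes, and 21 of its 147 calls were unchanged genes. edgeR called 34% and 95%, with 28 unchanged of 157, and DESeq2 48% and 96%, with 45 unchanged of 189. All 3 thus made more false calls than the threshold of 0.05 sets. This was a single draw, the changed genes all had a mean of at least 50, and no simulated library stood apart from the others. Only 12 genes passed limma in the real data, so its adjustment was stricter there and the shares called do not carry over. Fosb (13.2-fold lower) and Bglap (8.06-fold lower), for instance, did not pass. A shifted list of 25 genes was called, and 0 of 100 unshifted lists were. The genes were drawn independently, so this does not cover lists whose members move together. In the real data the estimated correlation was 0.48 for the T cell, NK cell and innate lymphoid list. It was 0.996 for the mitochondrially encoded list, 0.90 for heme biosynthesis, 0.81 for erythroid, 0.75 for plasma cell, 0.69 for eosinophil and 0.68 for ribosomal genes. Other lists had lower values, such as 0.019 for S phase. Where members move together, the count of members on one side of 0 is no test of a list, and the preset correlation of 0.01 is too low.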

Results

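RNA from lineage-negative (Lin–) bone marrow cells, the fraction left after cells bearing markers of mature blood lineages are removed, was sequenced from 2-month-old mice. 2 mice carried the floxed Tet3 alleles alone (Tet3F/F, labelled control) and 2 carried them with Cre driven by Tie2 (Tie2+/cre; Tet3F/F, labelled cKO). Tie2 (Tek) is active in endothelial and early blood cells, and TET3 oxidises 5-methylcytosine in DNA. The comparison asks which transcripts differ in Lin– cells when Tet3 is targeted. The reads counted to genes were 39199593 and 46673855 in the libraries labelled control (replicates 1 and 2) and 28845037 and 30020188 in those labelled cKO, over 16673 genes. The totals labelled control exceed the reads per sample that the labels state, and whether reads or read pairs were counted is not given in the sources used here. Levels are given as normalized counts, mean ± SD with n = 2 mice per group, and fold changes as cKO minus control on the log2(normalized count + 1) scale, which understates the change of low genes.

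Tet3 transcripts were not lower in the libraries labelled cKO. The gene had 5056 and 6593 normalized counts in the libraries labelled control and 6400 and 5084 in those labelled cKO, a log2 fold change of -0.02 (SE 0.22, 95% interval -0.53 to 0.49). Its adjusted p was 0.99 with limma and Benjamini-Hochberg adjustment. A count over the whole gene includes exons outside the floxed part, and the labels do not say which exons are floxed, so this value checks neither the genotype nor the labels. Because the targeted gene was not lower, each direction below is that of the libraries labelled cKO against the libraries labelled control. The related genes Tet1 (log2 fold change 0.61, SE 0.25) and Tet2 (0.15, SE 0.23) did not pass the test. Neither did the DNA methyltransferase genes Dnmt1 (0.28, SE 0.27), Dnmt3a (0.31, SE 0.21) and Dnmt3b (0.10, SE 0.19), or Tek, whose promoter drives Cre (0.91, SE 0.41). All 7 values moved with single libraries. Without control replicates 1 and 2 in turn, Tek had 0.38 and 1.44, Dnmt3a 0.49 and 0.12, Dnmt1 0.63 and -0.08 and Tet3 -0.21 and 0.17. Without cKO replicates 1 and 2 in turn, Tet1 had 0.34 and 0.87, Tet2 -0.12 and 0.42 and Dnmt3b 0.01 and 0.18.

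The groups differed in the sex of the mice, which the labels do not give. Xist, the RNA that coats the inactive X chromosome of female cells, had 5.54 and 9.57 normalized counts in the libraries labelled control and 87442 and 48951 in those labelled cKO (log2 fold change 12.94, SE 0.36; limma with Benjamini-Hochberg adjusted p = 1.84e-05). Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, had 0 reads in both libraries labelled cKO. Against a floor of 3 reads per library they were at least 983-fold, 1020-fold, 323-fold and 229-fold lower there. Both libraries labelled control thus carried male transcripts and both labelled cKO female ones, so genotype and sex cannot be separated in any comparison given here. Kdm6a, an X-linked histone demethylase gene that escapes X inactivation, had a log2 fold change of 0.90 (SE 0.20) and did not pass the test. The median log2 fold change was 0.08 over 515 tested X genes and 0.01 over 15588 autosomal genes.

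Of 16598 genes tested, 5 rose and 7 fell in the libraries labelled cKO at an adjusted p under 0.05, all 12 by at least 2-fold. Besides Xist and the 4 Y genes, 7 genes passed. Magi1, a scaffold protein of cell junctions, fell from 546 ± 159 to 20.9 ± 3.51 normalized counts (log2 fold change -4.62, SE 0.44; limma with Benjamini-Hochberg adjusted p = 0.019). Capn11, a calpain protease gene, had 171 and 200 normalized counts in the libraries labelled control and 0 reads in both labelled cKO, at least 53.4-fold lower. Eif3j2, which encodes a translation initiation factor subunit, rose from 96.4 ± 9.95 to 757 ± 120 (2.96, SE 0.31; limma with Benjamini-Hochberg adjusted p = 0.034). Gimap4, a GTPase gene of lymphocytes, rose from 411 ± 7.93 to 1993 ± 534 (2.25, SE 0.25; limma with Benjamini-Hochberg adjusted p = 0.045). Igkv6-15, an immunoglobulin kappa variable segment, rose from 348 ± 85.6 to 2363 ± 741 (2.74, SE 0.30; limma with Benjamini-Hochberg adjusted p = 0.041). The predicted gene Gm42047 had 3285 and 5944 reads in the libraries labelled control and 0 in both labelled cKO, at least 1119-fold lower. The predicted gene Gm49980, which has no chromosome in the annotation used here and so could lie on X, had 1 and 0 reads in the libraries labelled control and 832 and 818 in those labelled cKO.

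**Figure D1:**
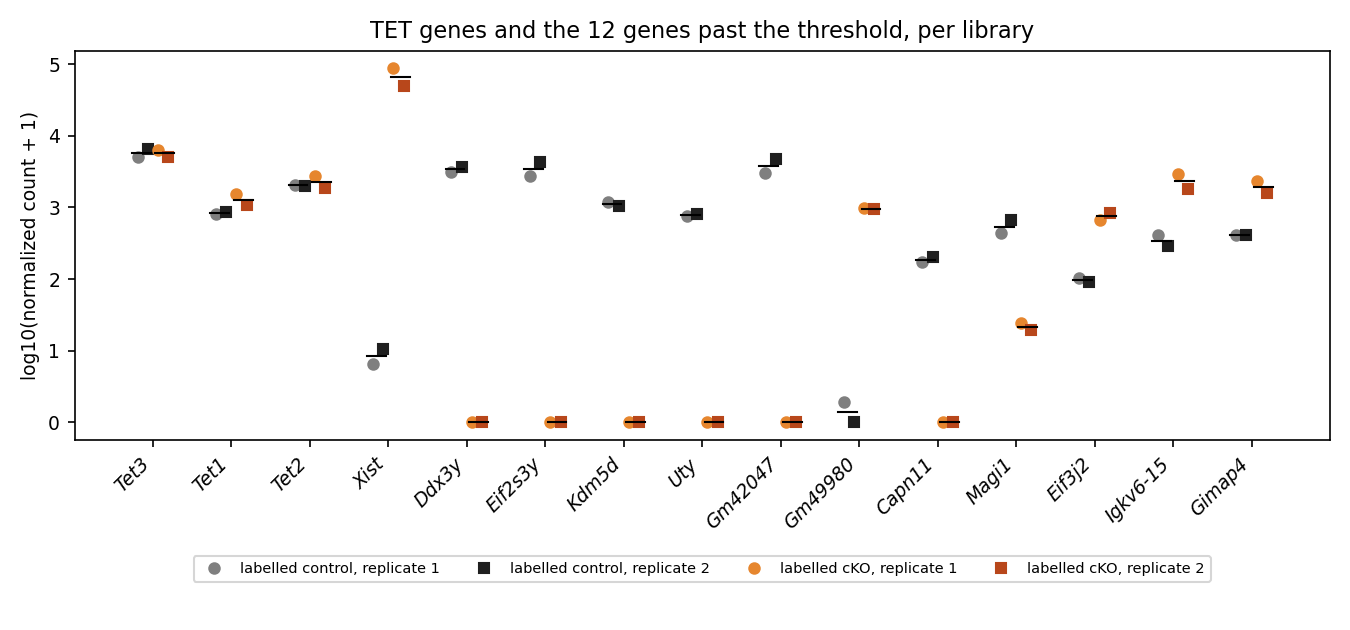
Normalized counts of the 3 TET genes and of the 12 genes past the threshold, one point per library, as log10(normalized count + 1); circles are replicate 1, squares replicate 2, and bars the mean of the logged values of each group (n = 2). The TET genes lie close together, while 6 genes have 0 reads in both libraries labelled cKO.

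Eif3j2 has a near-identical copy, Eif3j1, between which the counting could split reads. Eif3j1 had 3834 normalized counts on average in the libraries labelled control and 2534 in those labelled cKO, and the sum of both genes had a log2 fold change of -0.26 (SE 0.19), so the rise of Eif3j2 is uncertain. Kappa segments such as Igkv6-15 also share sequence, and their counts are uncertain for the same reason. Of these 7 genes, 6 on autosomes and the unplaced Gm49980, Gm42047 and Gm49980 alone kept their call when genes placed on X and Y were left out of the test, since the adjustment then lost its strongest p-values. Without control replicate 2, Magi1, Capn11, Gimap4 and Igkv6-15 lost theirs (limma with Benjamini-Hochberg, adjusted p 0.088, 0.15, 0.063 and 0.057). Gimap4 and Eif3j2 lost theirs without cKO replicate 1 (0.13 and 0.061), and Eif3j2 without cKO replicate 2 (0.19). Capn11, Eif3j2, Gimap4 and Igkv6-15 lost theirs with a mean of at least 50 (0.13, 0.051, 0.061 and 0.058) and with quantile normalization (0.063, 0.063, 0.069 and 0.069), Capn11 and Gimap4 with a pseudocount of 0.5 (0.076 and 0.052), and Magi1, Eif3j2, Gimap4 and Igkv6-15 without a variance trend (0.18, 0.27, 0.65 and 0.65). Where these calls ended, the log2 fold changes ran from -4.62 to -4.32 for Magi1 and 2.79 to 3.12 for Eif3j2. They ran from 1.97 to 2.25 for Gimap4 and 2.49 to 2.74 for Igkv6-15. For Capn11 they ran from -8.53 to -7.42, sizes that depend on the pseudocount, since both libraries labelled cKO had 0 reads. These are not measured folds, and the bound from the floor of 3 reads is at least 53.4-fold lower. DESeq2 on the recovered reads called 74 higher and 38 lower. Leaving out control replicate 1 raised the number of calls, but the only control left was then replicate 2, which stood apart from the other libraries (below). That rise is therefore no sign of more changes with genotype. Leaving out either cKO replicate also gave more lower genes.

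The genes next in rank by p-value did not pass the test. Among the higher ones were genes of T and natural killer (NK) cells, namely Klrb1c, an NK receptor (log2 fold change 2.33, SE 0.33), Cxcr6 (1.92, SE 0.27) and Cxcr3 (1.69, SE 0.29), chemokine receptors, Itga1 (1.40, SE 0.24) and Art2b (2.25, SE 0.37). Thbs1, which encodes thrombospondin (1.80, SE 0.25), Mmp9, a matrix protease (2.44, SE 0.36), Myl10 (2.50, SE 0.38) and Clec9a, a dendritic cell receptor (1.36, SE 0.23), were also among them. The lower ones held the immediate early genes Fos (-2.36, SE 0.30), Fosb (-3.72, SE 0.51), Jun (-2.00, SE 0.33), Egr1 (-2.36, SE 0.45), Nr4a1 (-1.70, SE 0.29) and Zfp36 (-1.23, SE 0.20). They also held the bone matrix genes Col1a1 (-2.16, SE 0.41), Bglap (-3.01, SE 0.56) and Sparc (-1.75, SE 0.26), and the lipase gene Lpl (-1.15, SE 0.21). DESeq2 on the recovered reads called each of these genes.

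The T cell, NK cell and innate lymphoid list was higher in the libraries labelled cKO. All 21 members had a log2 fold change above 0, with a median of 1.48, and in 17 of them both libraries labelled cKO lay above both labelled control. Chance gives 16.7% for a gene taken alone. The members moved together (estimated correlation 0.48), so the count of 17 is no test of the list. Among these 17 were Il2rb, a cytokine receptor chain (899 ± 284 against 2698 ± 604 normalized counts), Skap1, an adaptor of T cell signalling (121 ± 40.2 against 471 ± 98.7), and Cd3g, a chain of the T cell receptor complex (94.7 ± 64.7 against 472 ± 72.5). No member passed over all genes, and 12 were higher when adjusted over the list alone. The camera test with Benjamini-Hochberg adjustment gave an adjusted p = 1.14e-15, and the adjusted p = 0.71 with an estimated correlation. With each library left out in turn the median ran from 1.04 to 1.90, and the list stayed called.

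Other lymphoid and antigen-presenting lists were also called higher by camera. The plasma cell list (9 of 10 members above 0, median 0.89) held Jchain, the joining chain of secreted antibody (7988 ± 3635 against 15978 ± 2169), Igkc (20280 ± 15232 against 53325 ± 5522), Igha and Sdc1. Its members moved together (estimated correlation 0.75), so the count of 9 is no test. Its camera, Benjamini-Hochberg adjusted p was 7.83e-05 and the adjusted p = 0.71 with an estimated correlation, and the median ranged from 0.48 without control replicate 2 to 1.41 without control replicate 1. The B cell list (15 of 18, median 0.47, camera and Benjamini-Hochberg adjusted p = 0.012, adjusted p = 0.71 with an estimated correlation) held Blnk, a B cell adaptor (183 ± 11.97 against 508 ± 224), while its member Bst1 had a log2 fold change of -1.10. The dendritic cell list (10 of 15, median 0.45, camera and Benjamini-Hochberg adjusted p = 0.012, adjusted p = 0.71 with an estimated correlation) held Clec9a (390 ± 17.2 against 999 ± 53.1) and Siglech (1091 ± 99.1 against 1899 ± 721). The MHC class II list (7 of 9, median 0.40, camera and Benjamini-Hochberg adjusted p = 0.0083, adjusted p = 0.71 with an estimated correlation) held Cd74, the invariant chain (2386 ± 521 against 3803 ± 279), and H2-Ob. No member of these 4 lists passed over all genes, and adjusted over the list alone only Clec9a did. The B cell and dendritic calls ended without control replicate 1 (camera with Benjamini-Hochberg, adjusted p 0.21 and 0.55) and without cKO replicate 1 (0.76 and 0.45), and their medians ran from 0.13 to 1.09 and from 0.24 to 0.70 with each library left out. The B cell call also ended with a mean of at least 50 (0.068). The MHC class II call ended without control replicate 1 (0.070) and without cKO replicate 2 (0.14).

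The immediate early and dissociation stress list was lower in the libraries labelled cKO. Of 22 members, 18 had a log2 fold change below 0, the median was -0.89, and in 14 both libraries labelled cKO lay below both labelled control. Fos, a subunit of the AP-1 transcription factor, had 2930 ± 456 normalized counts in the libraries labelled control and 592 ± 239 in those labelled cKO. Fosb (212 ± 38.6 against 15.05 ± 1.47), Jun (1433 ± 518 against 353 ± 98.2) and Zfp36, an mRNA decay factor (3362 ± 571 against 1421 ± 53.7), had the next smallest p-values. None passed over all genes, and 9 were lower when adjusted over the list alone. The camera adjusted p with Benjamini-Hochberg adjustment was 5.49e-11, and the adjusted p = 0.71 with an estimated correlation. The median ran from -1.19 to -0.67 with each library left out, and the list stayed called.

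The bone marrow stromal and osteolineage list was called lower (camera with Benjamini-Hochberg adjusted p = 0.032, adjusted p = 0.71 with an estimated correlation), and its members went both ways, 8 above 0 and 10 below, with a median of -0.07 and a mean of -0.56. Col1a1 and Col1a2, the chains of type I collagen, had 9183 ± 1545 against 2279 ± 1443 and 6888 ± 253 against 1948 ± 1281. Sparc, a matrix protein (1848 ± 152 against 560 ± 166), and Bglap, osteocalcin (515 ± 320 against 60.1 ± 28.8), were the other members lower when adjusted over the list alone, 4 in all, and none passed over all genes. The call ended without control replicate 1 and without control replicate 2 (camera with Benjamini-Hochberg, adjusted p 0.094 and 0.20) and with a mean of at least 50 (0.11), and the median ran from -0.28 to -0.24 with each library left out.

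**Figure D2:**
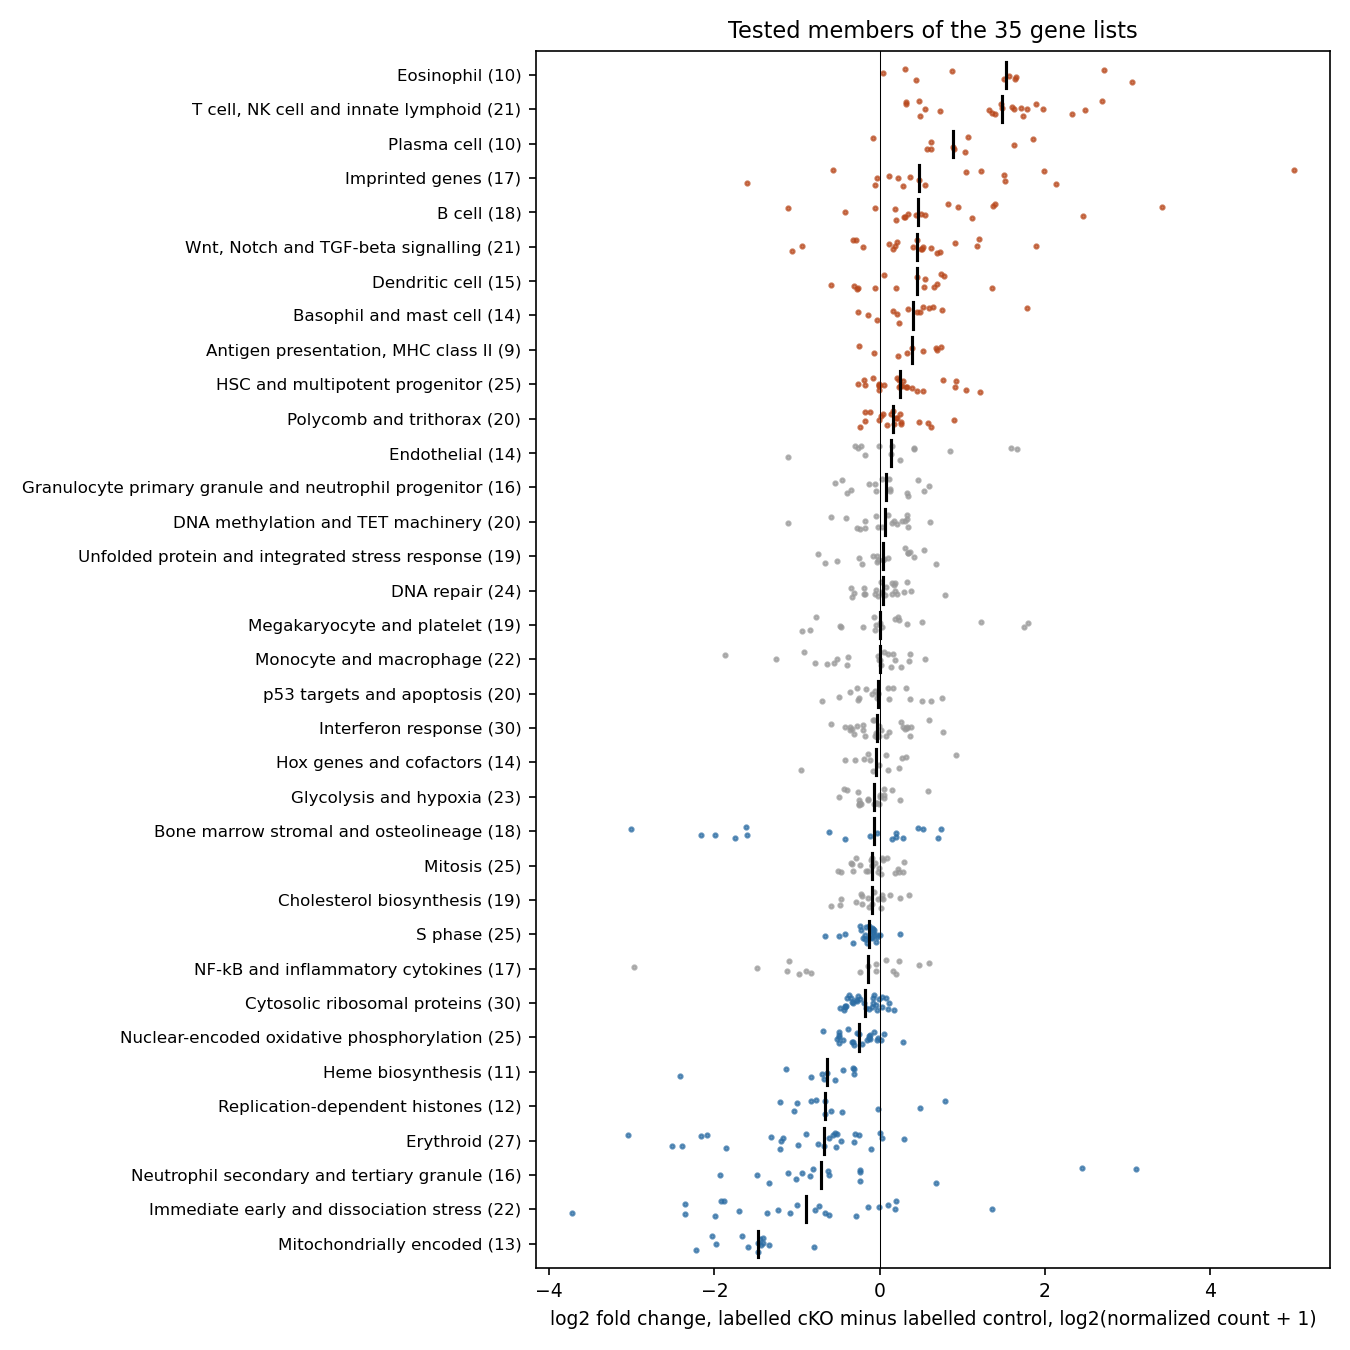
Log2 fold changes (cKO minus control) of the tested members of 35 gene lists, one point per gene, with the number of tested members in brackets and a black bar at each median. Orange marks lists called higher by camera and blue lists called lower at an adjusted p under 0.05 with the preset correlation, grey those not called; all 21 members of the T cell, NK cell and innate lymphoid list lie above 0.

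Myeloid, erythroid and stem cell lists moved with single libraries. Control replicate 2 stood apart from the other 3 libraries. Its correlations with them over genes, which are not independent replicates, were 0.93 to 0.95, and it lay at 96.2 on a first principal component that held 56.9% of the variance. Reads of the 13 mitochondrial protein genes made up 8.16% of its total (Wilson 95% interval 8.157 to 8.173), against 1.09%, 1.26% and 0.99% in control replicate 1 and cKO replicates 1 and 2. The 4 haemoglobin genes took 0.115% of it, against 0.0349%, 0.0447% and 0.00358%. These intervals cover counting error only.

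The erythroid list was called lower (24 of 27 members below 0, median -0.68, camera with Benjamini-Hochberg adjusted p = 1.91e-05, adjusted p = 0.71 with an estimated correlation). Hba-a1 had 7129 and 25005 normalized counts in the libraries labelled control and 7694 and 716 in those labelled cKO, and Hbb-bs had 4270, 13553, 5966 and 354. The heme biosynthesis list was called lower too (11 of 11 below 0, median -0.63, camera with Benjamini-Hochberg adjusted p = 8.85e-05, adjusted p = 0.71 with an estimated correlation), with Alad at 8610 ± 5479 against 3514 ± 5.29. Members of the erythroid and heme lists moved together (estimated correlation 0.81 and 0.90), so their counts below 0 are no test. Without control replicate 2 the erythroid median was 0.02 and the heme median -0.08, and neither was called (camera with Benjamini-Hochberg, adjusted p 0.13 and 0.25). The erythroid call also ended without cKO replicate 2 (0.11). No member of either list passed over all genes or adjusted over the list alone.

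The stem cell and multipotent progenitor list was called higher (17 of 25 members above 0, median 0.24, camera with Benjamini-Hochberg adjusted p = 0.0045, adjusted p = 0.71 with an estimated correlation). Of its members 10 are also in another list, such as Flt3 in the dendritic cell list, and Thy1 is also expressed by T cells. Thy1 had 653 ± 176 against 1514 ± 398 normalized counts, Fgd5 104 ± 26.8 against 213 ± 19.6, Ly6a 338 ± 94.6 against 564 ± 6.72 and Flt3, a cytokine receptor of progenitors, 5025 ± 37.9 against 6898 ± 790. The median was 0.50 without control replicate 2 and -0.05 without control replicate 1, where the call ended (camera with Benjamini-Hochberg, adjusted p 0.80). The eosinophil list was called higher (10 of 10, median 1.54, camera with Benjamini-Hochberg adjusted p = 0.00055, adjusted p = 0.71 with an estimated correlation), with Alox15 at 202 ± 132 against 563 ± 18.7. Its members moved together (estimated correlation 0.69), so the count of 10 is no test. Its median was 0.05 without control replicate 2, where it was not called (camera with Benjamini-Hochberg, adjusted p 0.48). The basophil and mast cell list was called higher (11 of 14 above 0, median 0.40, camera with Benjamini-Hochberg adjusted p = 0.046, adjusted p = 0.71 with an estimated correlation). It lost its call without control replicate 2 (median 0.02) and without cKO replicate 1 (median -0.01), and its median was 0.86 without control replicate 1. The call also ended with a mean of at least 50 and with quantile normalization (camera with Benjamini-Hochberg, adjusted p 0.10 and 0.051). Ms4a2, a member of this list, had 1233 ± 558 against 1743 ± 676. No member of these 3 lists passed over all genes or adjusted over the list alone.

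The neutrophil secondary and tertiary granule list was called lower (13 of 16 members below 0, median -0.71, camera with Benjamini-Hochberg adjusted p = 0.043, adjusted p = 0.79 with an estimated correlation). Mcemp1 had 1586 ± 37.9 against 656 ± 275 normalized counts and Camp, cathelicidin, 346 ± 236 against 99.7 ± 86.5, while Mmp9, a granule protease, had 75.5 ± 2.95 against 420 ± 95.6. Adjusted over the list alone 1 member was higher and 1 lower, and none passed over all genes. The median was 0.09 without control replicate 1 and 0.08 without cKO replicate 1, and the call ended in both (camera with Benjamini-Hochberg, adjusted p 0.74 and 0.62), as it did with a mean of at least 50 (0.074) and with quantile normalization (0.051). Lists not called were those of the primary granule (median 0.07), monocyte and macrophage (0.00), megakaryocyte and platelet (0.01) and endothelial genes (0.14), with camera and Benjamini-Hochberg adjusted p of 0.84, 0.13, 0.32 and 0.22. The primary granule list was called higher without control replicate 1 (median 0.70, camera with Benjamini-Hochberg adjusted p = 0.00016) and lower without control replicate 2 (-0.57, 1.07e-08). Without control replicate 2 the megakaryocyte list was called higher (0.41, 1.24e-05) and the monocyte list lower (-0.56, 8.62e-05), as the latter was without cKO replicate 2 (-0.43, 0.0017). In the megakaryocyte list, Thbs1 (481 ± 73.3 against 1684 ± 332) and Selp, P-selectin (97.2 ± 6.91 against 333 ± 70.1), were higher when adjusted over the list alone. Gfi1, a repressor in granulocyte precursors, had 3108 ± 430 against 2283 ± 526.

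**Figure D3:**
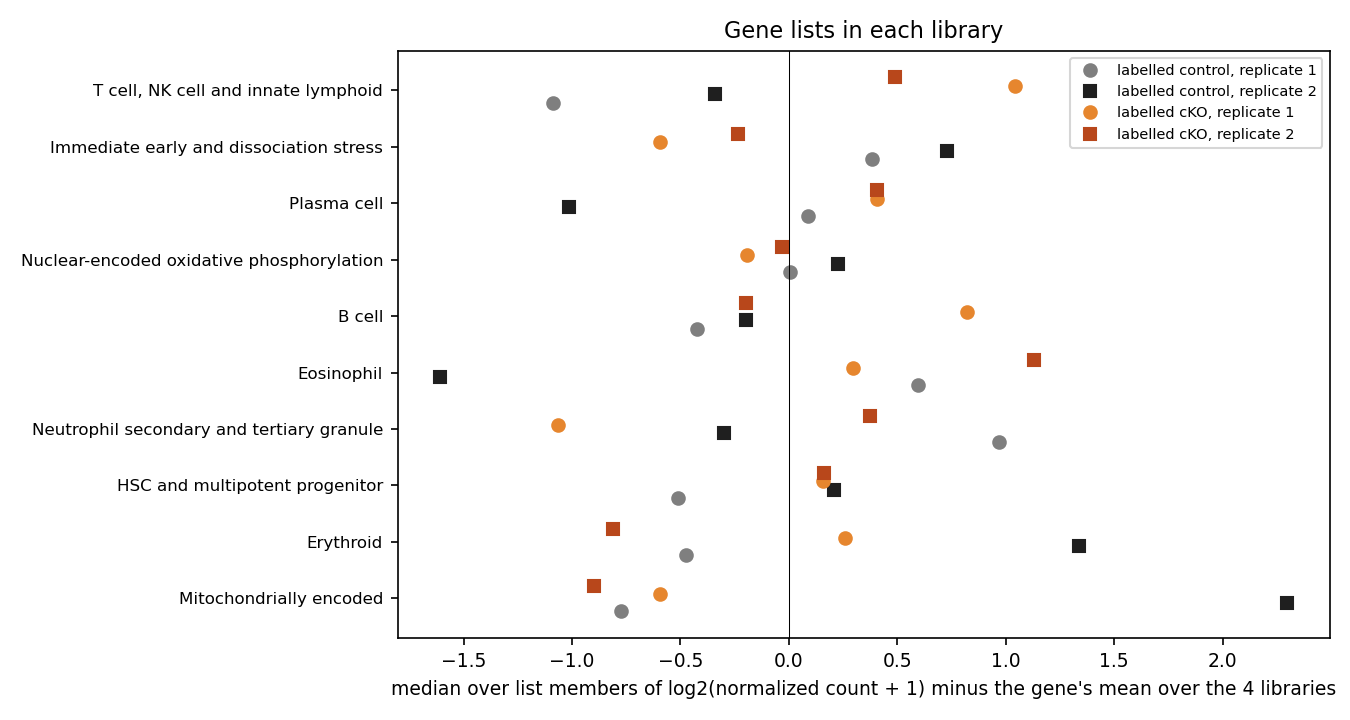
Median over the members of 10 gene lists of log2(normalized count + 1) minus the gene's mean over the 4 libraries, one point per library. Control replicate 2 lies at 2.30 in the mitochondrially encoded list and at 1.34 in the erythroid list, above the other 3 libraries, while in the T cell, NK cell and innate lymphoid list both libraries labelled control lie below both labelled cKO.

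The mitochondrially encoded list was called lower (13 of 13 members below 0, median -1.47, camera with Benjamini-Hochberg adjusted p = 1.59e-05, adjusted p = 0.71 with an estimated correlation). Its members moved together (estimated correlation 0.996), so the count of 13 is no test. The mt-Nd1 gene, a complex I subunit, had 52711 and 403457 normalized counts in the libraries labelled control and 50762 and 41884 in those labelled cKO. Without control replicate 2 the median was 0.02 and the list was not called (camera with Benjamini-Hochberg, adjusted p 0.82). The nuclear-encoded oxidative phosphorylation list was lower by a small amount (22 of 25 below 0, median -0.25, camera with Benjamini-Hochberg adjusted p = 0.00051, adjusted p = 0.71 with an estimated correlation). Cox4i1, a subunit of cytochrome c oxidase, had 16416 ± 4656 against 11490 ± 1530 and Ndufa2 2790 ± 1424 against 1622 ± 11.1. The median of this list ran from -0.32 to -0.14 with each library left out, and the list stayed called. Relative to each gene's mean over the 4 libraries, the list median was 0.23 in control replicate 2 and -0.19 in cKO replicate 1. Control replicate 1 and cKO replicate 2 lay close together, at 0.005 and -0.03. The difference thus leaned on control replicate 2, which stood apart, and on cKO replicate 1, and no single library left out removes both. No member of either list passed over all genes or adjusted over the list alone.

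The S phase, ribosomal and histone lists were called lower. For the S phase list, 23 of 25 members lay below 0 (median -0.13, camera with Benjamini-Hochberg adjusted p = 0.010, adjusted p = 0.71 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, had 10707 ± 559 against 7630 ± 294 and Ccne1, cyclin E1, 2573 ± 1164 against 1544 ± 31.4. For cytosolic ribosomal proteins, 24 of 30 lay below 0 (median -0.18, camera with Benjamini-Hochberg adjusted p = 0.012, adjusted p = 0.79 with an estimated correlation), among them Rpl18 at 38803 ± 7934 against 28542 ± 3355. For replication-dependent histones, 10 of 12 lay below 0 (median -0.66, camera with Benjamini-Hochberg adjusted p = 0.013, adjusted p = 0.71 with an estimated correlation), among them the linker histone H1f2 at 989 ± 326 against 541 ± 11.1. The S phase call ended without control replicate 1 and without cKO replicate 1, and the ribosomal and histone calls without control replicate 2 and without cKO replicate 1. With each library left out, the medians ran from -0.17 to -0.11 (S phase), -0.36 to -0.05 (ribosomal) and -1.06 to -0.36 (histones). With quantile normalization the S phase and ribosomal calls ended (camera with Benjamini-Hochberg, adjusted p 0.093 and 0.79). No member of these 3 lists passed over all genes or adjusted over the list alone.

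Among epigenetic and signalling lists, the DNA methylation and TET machinery was not called (11 of 20 members above 0, median 0.06, camera with Benjamini-Hochberg adjusted p = 0.84). The Polycomb and trithorax list was called higher (15 of 20, median 0.16, camera with Benjamini-Hochberg adjusted p = 0.042, adjusted p = 0.71 with an estimated correlation), led by the X-linked Kdm6a (1753 ± 54.4 against 3301 ± 584) and by Kmt2c, a histone methyltransferase gene (3100 ± 221 against 4774 ± 1500). The imprinted list was called higher (13 of 17, median 0.48, camera with Benjamini-Hochberg adjusted p = 0.010, adjusted p = 0.71 with an estimated correlation). Its noncoding RNA Rian had 4 and 0 reads in the libraries labelled control and 42 and 84 in those labelled cKO, the only member higher when adjusted over the list alone, while Dcn had a log2 fold change of -1.60. The Wnt, Notch and TGF-beta list was called higher (16 of 21, median 0.46, camera with Benjamini-Hochberg adjusted p = 0.0040, adjusted p = 0.71 with an estimated correlation). Lef1, a Wnt pathway transcription factor also used by T cells, had 51.8 ± 15.8 against 191 ± 15.3 and Axin2, a Wnt target, 60.8 ± 9.31 against 139 ± 24.5, while Id1 had 421 ± 0.478 against 224 ± 66.2. No member of these lists passed over all genes. The Polycomb, Wnt and imprinted calls ended without control replicate 1, where the medians were 0.17, 0.43 and 0.22. With each library left out, these medians ran from 0.06 to 0.28, from 0.23 to 0.59 and from 0.22 to 0.89. The Polycomb call also ended without X and Y genes (camera with Benjamini-Hochberg, adjusted p 0.11) and without cKO replicate 1 (0.66), and the imprinted call without cKO replicate 2 (0.11) and with a mean of at least 50 (0.38).

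The remaining lists were not called by camera with Benjamini-Hochberg adjustment. They were Hox genes and cofactors (median -0.05, adjusted p 0.84), interferon response (-0.03, 0.90), NF-kB and inflammatory cytokines (-0.14, 0.064), mitosis (-0.09, 0.19), p53 targets and apoptosis (-0.02, 0.99), glycolysis and hypoxia (-0.06, 0.15), cholesterol biosynthesis (-0.10, 0.15), the unfolded protein and integrated stress response (0.05, 0.99) and DNA repair (0.04, 0.65). Mitosis was called lower without cKO replicate 1 (median -0.19, camera with Benjamini-Hochberg adjusted p = 0.0087), and glycolysis (-0.34, 1.56e-05) and cholesterol biosynthesis (-0.12, 0.010) without control replicate 2. In all, camera called 21 of 35 lists, 11 higher and 10 lower. With an estimated correlation it called 0, and 0 had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom, so its lack of calls does not show the lists unchanged. Nor does it back the calls made at the preset correlation. The fry test called 0, with 4 at an unadjusted p under 0.05. Germline genes methylated in somatic cells had 2 tested members of 18 and were not tested as a list.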

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

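The test without X and Y genes was chosen after the results were seen, and the others were planned. The cause of a change was not tested except where given. Of the 12 called genes, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Gm42047 and Gm49980 passed under every alternative that held them. Of 16 alternatives, Magi1 passed under 12, Igkv6-15 under 11, Capn11 under 10, Eif3j2 under 9 and Gimap4 under 8. The 5 genes higher in cKO became 2 with a mean of at least 50, 2 with quantile normalization, 2 without a variance trend, 3 with the replicate block, 1 without X and Y genes and 74 with DESeq2 on recovered reads. The 7 lower became 1 without X and Y genes and 38 with DESeq2, and the 12 changed at least 2-fold became 2 and 106. Without X and Y genes the strongest p-values leave the adjustment, which lowers the number that pass. With each library left out in turn, the counts ran from 4 to 232 higher, 5 to 161 lower and 10 to 375 changed at least 2-fold, the highest each time without control replicate 1. The lone library of a group is then assumed to vary like the other group. Without control replicate 1 that lone library was control replicate 2, which stood apart, so those counts cannot be read as changes with genotype.

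The replicate numbers showed no pairing of the libraries, although so few libraries, with control replicate 2 apart from the others, cannot exclude one. The correlation of deviations between libraries of the same number was -0.07, and the block gave 3 genes higher and 5 lower and 20 called lists. Under it the calls of Magi1, Capn11, Eif3j2 and Gimap4 ended.

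Of the 21 called lists 0 stayed called with an estimated correlation and 0 with fry. Called in the same direction were 11, 13, 13 and 18 of them without control replicates 1 and 2 and cKO replicates 1 and 2, while all lists called there, new ones included, ran from 12 to 19. With a mean of at least 50 they became 16, losing the secondary and tertiary granule, basophil and mast cell, B cell, stromal and imprinted lists. With quantile normalization they became 17, losing the secondary and tertiary granule, basophil and mast cell, S phase and ribosomal lists. Without X and Y genes they became 20, losing the Polycomb and trithorax list, and the block lost the secondary and tertiary granule list. The T cell, NK cell and innate lymphoid, plasma cell, immediate early and nuclear-encoded oxidative phosphorylation lists were called under every camera setting with the preset correlation.

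The log2 fold change of Tet3 was 0.020 with quantile normalization and ran from -0.21 to 0.17 with each library left out. The ranges of other genes that changed sign were -0.12 to 0.42 for Tet2, -0.076 to 0.63 for Dnmt1, -0.26 to 1.33 for Calr and -0.51 to 1.14 for Ly6c2. None of these genes passed with all 4 libraries.

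With quantile normalization the direction of camera turned for the primary granule list (median 0.12), interferon response (-0.030), p53 targets (-0.016) and cytosolic ribosomal proteins (-0.0028), of which only the last had been called. It turned for the unfolded protein response with TMM rescaling (0.060), for p53 targets (-0.023) and the unfolded protein response (0.045) with the replicate block, and for the DNA methylation machinery without X and Y genes (0.0075). These medians lie near 0. With each library left out, the direction turned for these lists, given as ranges of the median: stem cell and multipotent progenitor -0.047 to 0.50, erythroid -1.69 to 0.017, megakaryocyte -0.49 to 0.41, primary granule -0.57 to 0.70, secondary and tertiary granule -1.36 to 0.087, monocyte -0.56 to 0.23, DNA methylation machinery 0.017 to 0.23, Hox -0.17 to 0.22, interferon -0.066 to 0.18, mitosis -0.19 to 0.042, p53 targets -0.028 to 0.0060, mitochondrially encoded -3.06 to 0.022, glycolysis -0.34 to 0.13, unfolded protein response -0.10 to 0.26 and DNA repair -0.020 to 0.11. Read depth limits the folds of genes at 0 in a group, which are lower bounds.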

Other observations

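The groups and tests in this part were chosen after the results were seen. The T cell, neutrophil granule and erythroid lists and their medians with a library left out were planned, but their use here was not. Immunoglobulin variable segments were higher in the libraries labelled cKO. Of 80 kappa segments 75 had a log2 fold change above 0 (median 2.00) and in 43 both libraries labelled cKO lay above both labelled control. Chance gives 16.7% for a segment taken alone, but segments can move together, so these counts are no test. Of 83 heavy chain segments 79 lay above 0 (median 2.18), with 45 above both. Over all genes limma passed 1 kappa segment and 0 heavy chain segments, with 34 of each at an unadjusted p under 0.05, edgeR passed 1 and 0, and DESeq2 6 and 4. Control replicate 2 set much of the size, since without it the medians were 0.68 and 0.63. Adjusted over 6 such groups by Benjamini-Hochberg, camera gave adjusted p = 8.68e-23 and 9.63e-22, and adjusted p = 0.26 for both with an estimated correlation. The groups were chosen after these same data were seen, and the adjustment does not cover that choice, so these p-values are no test either. Segments share sequence, so single counts are uncertain.

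Gimap genes, GTPases of lymphocytes, were above 0 in 9 of 9 (median 0.99, and 1.42 without control replicate 2), Klr genes, NK receptors, in 18 of 19 (1.44 and 1.70), and gamma T cell receptor constant genes in 3 of 3 (1.98 and 2.48). Camera with Benjamini-Hochberg gave adjusted p = 1.69e-09, 1.36e-07 and 7.21e-06, and adjusted p = 0.26 for each with an estimated correlation. As for the segments, these p-values are no test, since the groups were chosen after the data were seen. Over all genes limma passed 1, 0 and 0 of them, with 6, 9 and 3 at an unadjusted p under 0.05, edgeR passed 1, 0 and 0, and DESeq2 3, 2 and 2. The 26 collagen genes went both ways, 12 above 0 and 14 below (median -0.09), although Col1a1 and Col1a2 were among the lower genes.

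The higher T cell, NK cell and innate lymphoid list may reflect more such cells in the fractions labelled cKO or another difference between the mice, although the Lin– selection should remove mature T cells. Of its 21 genes 1 is in another list, and its most abundant, Ly6c2, which monocytes also express, had 46971, 14948, 29489 and 36852 normalized counts (control, then cKO), while Il2rb had 698, 1099, 3125 and 2271. Control replicate 2, the library that stood apart, was not the sole source, since the list median was 1.79 without it. A less complete removal of all mature cells stays open: the neutrophil secondary and tertiary granule list went the other way (median -0.71), but its median was 0.09 without control replicate 1, and the erythroid median was 0.02 without control replicate 2. A difference of sex between the groups cannot be told apart from genotype, because 0 groups held libraries of both sexes.

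Besides the Y genes, 4 genes had at least 50 reads in both libraries of one group and at most 3 in both of the other: Gm42047, Capn11, Gm49980 and Igkv4-63 (0 and 0 against 82 and 194 reads). Of these 3 lie on autosomes, and Gm49980 has no chromosome in the annotation used here, so linkage to X, and with it sex, stays open for it. The other splits of the 4 libraries gave at most 0, and 3 splits are too few for a share under 0.05. Igkv4-63 is a kappa segment, and 75 of 80 such segments had a log2 fold change above 0, so it may follow that rise. For the other genes, sequence variants between the mice, such as those of a mixed strain background, are a candidate explanation. They were not measured, and any that differed between the groups could not be told apart from genotype or sex with these 4 libraries.

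Chromosome 6, which carries Tet3, held 111 genes with an unadjusted p under 0.05 among 951, an odds ratio of 2.17 against other autosomes (Fisher's exact test, 95% interval 1.75 to 2.69). This interval and those below take genes as independent, which genes that move together are not, so they are likely too narrow. Lymphocyte gene families and the Clec genes, which had been seen among the genes with low p-values, are a possible source. With 143 immunoglobulin, T cell receptor, Klr, Clec and Gimap genes of the chromosome left out, the odds ratio was 1.16 (0.85 to 1.56). Leaving out families picked for their low p-values was likely to lower the ratio, so the drop is no test of this source. The Clec genes include some of other cells, such as the dendritic cell receptor gene Clec9a, so the drop is not that of lymphocyte genes alone. For sequence around Tet3, the 200 genes nearest to it had an odds ratio of 1.73 (1.01 to 2.79), but 26 of them belong to these families. The 200 nearest with the families left out had 1.002 (0.49 to 1.84), so these ratios decide nothing on sequence around Tet3. Of the called autosomal genes, Magi1, Gimap4 and Igkv6-15 lie on chromosome 6, and Gm42047, Capn11 and Eif3j2 on other chromosomes. With the families left out, Magi1 lies 109 tested genes from Tet3, just outside the 200 nearest. Both groups carry the floxed alleles, so variants held with those alleles would be shared and could not make the groups differ.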
